A study of Mus musculus with 12 samples.

How the data were processed

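Gene expression was measured by RNA sequencing in BV2 cells, an immortalized mouse microglial line. Per the labels, cells were kept in serum-free medium for at least 4 h from 24 h after seeding, received 6-gingerol or 6-shogaol, and received lipopolysaccharide (LPS, the endotoxin of Gram-negative bacteria that activates TLR4) at 100 ng/mL 1 h later. The time between LPS and harvest is not given. Total RNA was extracted with TRIzol, and stranded mRNA libraries (TruSeq) were sequenced in paired-end mode on a NovaSeq X. The 12 libraries form 6 groups of 2 replicates: untreated, LPS, and LPS with 10 or 30 µM of either compound. No label states whether replicates were separate cultures, so every p-value measures only the spread between these samples.

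Per the file headers, the deposited per-library tables are RSEM gene tables, whose expected count (estimated reads per gene, 7.03% of the values not whole) was the value used. Gene length and effective length, per the file headers in bases, were used only to obtain the mean fragment length of each library. A second deposited table holds a normalized signal per gene made by the authors. It lists 18013 genes, of which 15982 (88.7%) are in the per-library tables. Its ratio to the expected count lay within 1% of the library median for 23.8% of values, so it is not the expected count times 1 factor per library, and its normalization is not stated. Each of its 12 columns correlated best with its own library. The authors' notes name Trimmomatic 0.39, FastQC 0.12.1, STAR 2.7.11b, RSEM 1.3.3, R 4.4.2, DESeq2 1.44.0 and the genome build GRCm38, without the role or order of each or the annotation release. Of 43432 gene identifiers, 97.8% were matched to a symbol in the GENCODE M21 annotation, which also gave the positions.

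Library totals ran from 16534960 to 21179867 expected counts, and 20036 genes had at least 1 count. Expected counts were rounded and filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3), which kept 12705 genes. They were scaled by TMM and fitted for all 12 libraries together with 6 group means and no covariate, leaving 6 residual degrees of freedom. The edgeR quasi-likelihood F test with robust dispersion (common biological coefficient of variation 9.45%, median prior degrees of freedom 9.01) was run for 10 contrasts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast, over all genes tested. Every adjusted p of a single gene is from edgeR and is 2-sided. Levels are CPM (counts scaled to a common library size), given as mean ± SD of 2 libraries, changes are log2 fold changes with their standard error (SE), and intervals are 95%. The median half-width of a gene's interval was 0.29 on the log2 scale for each contrast of a pair of groups and 0.41 for the difference of the dose steps.

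The contrasts were LPS against untreated, each compound and dose against LPS, the compounds against each other at 10 and at 30 µM, 30 against 10 µM for each compound, and the difference between these dose steps. LPS-induced genes were those higher with LPS at an adjusted p under 0.05 and a log2 fold change of at least 1. The retained response of such a gene was its log2 change from untreated with LPS and compound, in percent of that with LPS alone. The LPS libraries enter both the selection and the comparison, so the same quantities were obtained from 40 simulations in which the compound groups did not differ from LPS. Simulated genes varied independently of each other. The simulations gave 478 LPS-induced genes on average against 370 observed, and a larger shared variance than the data: the covariance of the log2 fold changes of 6-gingerol at 10 and 30 µM was 0.00305 against a simulated 0.0146.

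Gene lists were tested with camera in limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01, adjusted over the 22 lists with enough measured genes within a contrast. Camera asks whether the genes of a list move differently from all other genes. It was repeated with a correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance in 1 direction. Members called over all genes were counted, and so were members called when edgeR p-values were adjusted over the list alone. The lists covered inflammatory cytokines and chemokines, the NF-kB pathway and its feedback, inflammatory effectors, the type I interferon response, NRF2 targets (antioxidant genes), HSF1 targets (heat shock chaperones), the ATF4 integrated stress response, chaperones of the unfolded protein response, cholesterol biosynthesis, LXR targets, glycolysis and hypoxia, DNA replication and G1/S, mitosis, p53 targets, immediate early genes, microglia identity, lysosome and autophagy, metallothioneins and zinc, the nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, and markers of astrocytes, neurons, oligodendrocytes, fibroblasts and endothelium, and lymphocytes and neutrophils.

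Groups, contrasts, lists, the rule for naming genes and most alternative settings were fixed before the data were examined. The rule took, per contrast, the 8 called genes with the largest change in each direction (4 for the dose contrasts) whose replicates did not overlap and whose CPM reached 5 in the higher group, without Gm- and Rik-named models. It added a fixed panel of 20 genes and up to 4 members with the smallest p per list. Not every gene that the rule took is described. The fixed alternatives were DESeq2 size factors or library totals for scaling, the DESeq2 1.42.0 Wald test, limma-voom, limma-trend on the authors' normalized table (genes with a value of at least 10 in 2 libraries, pseudocount 1), no count filter, a filter of 5 CPM in 2 libraries, a fit of the compared groups alone, a replicate term, a log2 change of at least 1, and leaving out each library in turn. Where that left a group with 1 library, its spread was taken from the other groups. Fragment length as a covariate, a fit without the untreated libraries and the bias-adjusted fit of edgeR (legacy = FALSE) were added after the data were seen. The procedure was tested on simulated data with a known effect: a 2-fold change was recovered for 79.1 to 91.0% of genes, and 3.8 to 9.7% of the calls were false, against the 5% aimed at. Each simulated contrast held 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. Plots were drawn with matplotlib 3.10.9.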

Results

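The transcriptomes of BV2 microglial cells were compared without treatment, after LPS, and after LPS with 6-gingerol or 6-shogaol, pungent phenols of ginger. 6-Shogaol is the dehydration product of 6-gingerol and carries an α,β-unsaturated ketone where 6-gingerol carries a β-hydroxy ketone. Each of the 6 groups held 2 libraries, and values are mean CPM ± SD with n = 2 throughout. Total expected counts were 19784878 and 20271750 in the untreated libraries, 16906954 and 21179867 with LPS, 19144016 and 18680256 with 10 µM 6-gingerol, 18723488 and 19870189 with 30 µM 6-gingerol, 16534960 and 19876803 with 10 µM 6-shogaol, and 16535052 and 18065906 with 30 µM 6-shogaol. Between 15345 and 16015 genes had at least 1 count in a library.

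The first principal component held 34.4% of the variance and placed LPS alone (20.17 and 19.56) beside 6-gingerol at 10 µM (20.4 and 20.08) and 30 µM (16.69 and 16.96). The 10 µM 6-shogaol libraries lay at 4.16 and 4.35, between LPS and untreated (-29.46 and -30.84), and the 30 µM 6-shogaol libraries at -31.24 and -30.85. On the second component (19.9%), 30 µM 6-shogaol (28.32 and 29.24) and untreated cells (-30.73 and -28.94) lay at opposite ends. The third (10.2%) separated the 2 untreated libraries, at 19.84 and -15.72, whose mean fragment lengths were 226 and 247 bases. It also set 10 µM 6-shogaol (-14.24 and -15.93, 246 and 247 bases) apart from LPS (5.36 and 9.59, 236 and 222 bases). The 30 µM 6-gingerol replicates lay at -13.89 and 8.51 (248 and 222 bases). The 30 µM 6-shogaol replicates went the other way, at -6.1 and 12.25 (235 and 243 bases). On the fourth (7.3%), replicate 1 of 10 µM 6-gingerol stood alone at -29.4, with the other 11 libraries between -5.37 and 12.99.

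**Figure D1:**
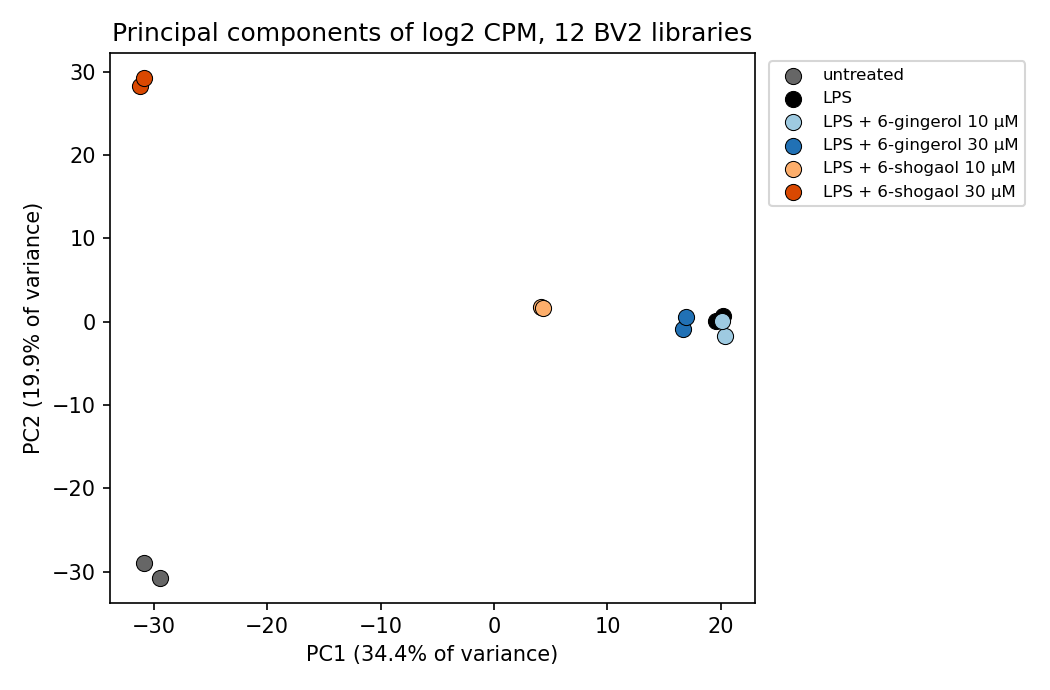
First and second principal components of log2 CPM, 1 point per library, coloured by group. LPS and 6-gingerol libraries lie together, 10 µM 6-shogaol lies between them and untreated cells on the first component, and 30 µM 6-shogaol is separated from untreated cells on the second.

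The first contrast asked what LPS did to the cells. Cfb, complement factor B (ENSMUSG00000090231, chromosome 17, 34856374 to 34862518), rose from 0.270 ± 0.053 to 263.9 ± 4.29 CPM, a log2 fold change of 9.91 (SE 0.17, adjusted p = 4.5e-15). Transcripts of secreted immune mediators rose with it: the chemokine Ccl5 from 1.51 ± 0.55 to 267.5 ± 29.9 CPM, Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), a chemokine for T cells, from 1.88 ± 0.11 to 251.0 ± 8.35 CPM, the cytokine Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981) from 8.04 ± 2.42 to 203.1 ± 13.1 CPM, and Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) from 16.0 ± 0.59 to 149.4 ± 7.21 CPM. Gbp2, Rtp4, Zbp1 and Lta were near 0 without LPS (0.026, 0.051, 0.098 and 0.070 CPM) and reached 18.4 ± 2.89, 6.51 ± 1.84, 7.14 ± 0.27 and 5.01 ± 0.96 CPM. In the other direction, Apoc1, an apolipoprotein, fell by 2.55 on the log2 scale (SE 0.29, adjusted p = 1.77e-05), C1qc and C1qb, chains of complement C1q, fell by 2.45 and 1.77, and the lipid carrier Apoe fell by 1.21, from 425.8 ± 18.3 to 184.2 ± 0.19 CPM.

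Of 17 measured cytokine and chemokine genes, 14 rose with LPS (15 rose when adjusted over the list alone), with a median log2 fold change of 2.36. Effectors rose in 22 of 26 cases (23 adjusted over the list alone, median 1.77), among them Acod1, which makes itaconate (92.8 ± 9.64 to 1178 ± 35.0 CPM), the acute-phase gene Saa3 (489.2 ± 85.7 to 13680 ± 562 CPM), the scavenger receptor Marco (27.5 ± 1.74 to 305.5 ± 3.65 CPM), Nos2, the inducible nitric oxide synthase (43.9 ± 8.76 to 191.7 ± 8.0 CPM), and Ptgs2, cyclooxygenase of prostaglandin synthesis (28.5 ± 3.67 to 83.3 ± 1.96 CPM). Interferon response genes rose in 32 of 35 cases (35 adjusted over the list alone, median 2.32), including Rsad2, Oasl1, Isg15 and Ifit1, antiviral genes with log2 fold changes of 5.22, 3.90, 4.29 and 4.47. In the NF-kB list 18 of 24 rose and 1, the surface protein Cd83, fell (21 and 1 adjusted over the list alone). Its signalling adaptor Traf1 had a log2 fold change of 5.19, and the feedback inhibitors Nfkbia and Tnfaip3 had 1.61 and 1.303. NRF2 targets rose in 16 of 31 cases and fell in 1, the protease Lgmn (19 and 2 adjusted over the list alone). Slc7a11, the cystine importer, went from 5.16 ± 0.54 to 69.1 ± 9.08 CPM, and Hmox1, heme oxygenase 1, from 228.9 ± 4.03 to 524.5 ± 25 CPM. Cd83 and Lgmn, which went against their lists, were named after their values were seen. Camera called these 5 lists higher (adjusted p = 6.51e-25, 4.72e-35, 4.65e-49, 2.4e-19 and 7.36e-12 in the order given). Each call held with an estimated correlation, at adjusted p = 0.00597, 0.000341, 0.00014, 0.00597 and 0.00846 in the same order. The p-values of the preset correlation were thus far smaller than those of the estimated one.

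Of 25 microglia identity genes 8 fell with LPS and 2 rose (11 and 2 adjusted over the list alone). Among them the receptor Trem2 fell by 0.63 on the log2 scale. The camera call of that list (adjusted p = 0.00214) was lost, with adjusted p = 0.111 with an estimated correlation. The calls for immediate early genes (7 higher and 1 lower of 27, 8 and 2 adjusted over the list alone), LXR targets (1 higher and 2 lower of 10, 1 and 3 adjusted over the list alone), mitochondrially encoded mRNAs (2 lower of 13, 3 adjusted over the list alone) and fibroblast and endothelial markers (2 higher of 3, 3 adjusted over the list alone) were lost as well, with adjusted p = 0.478, 0.446, 0.663 and 0.173 with an estimated correlation. Fry gave adjusted p = 0.00191 for microglia identity, 0.0237 for immediate early genes and 0.0129 for LXR targets. It gave 0.319 for mitochondrially encoded mRNAs and 0.00304 for fibroblast and endothelial markers. Without a camera call, fry also had p53 targets higher (adjusted p = 0.00124) and metallothioneins and zinc lower (0.00488). No camera call was made for 12 lists. Genes called in them, higher and lower, were 4 and 1 of 20 p53 targets (4 and 1 adjusted over the list alone), 1 and 1 of 22 HSF1 targets (1 and 1), and 3 and 3 of 34 ATF4 targets (3 and 5). Chaperones of the unfolded protein response had 2 and 0 of 22 (2 and 1), cholesterol biosynthesis 3 and 0 of 23 (3 and 0), glycolysis and hypoxia 2 and 4 of 28 (3 and 4), lysosome and autophagy 3 and 2 of 30 (3 and 2), and metallothioneins and zinc 0 and 1 of 6 (0 and 1). DNA replication and G1/S, mitosis, the nuclear-encoded respiratory chain and ribosomal proteins had no member called either way, with median log2 fold changes of -0.01, 0.04, -0.07 and 0.00. Markers of other brain and blood cells were too few to test: 2 of 9 astrocyte genes were measured, 0 of 9 neuron, 2 of 9 oligodendrocyte and 1 of 14 lymphocyte and neutrophil genes. The astrocyte gap junction gene Gja1 rose from 6.05 ± 0.006 to 16.2 ± 0.71 CPM.

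In edgeR 1501 of 12705 genes were called with LPS, 973 higher and 528 lower. Scaling by library totals split the calls into 785 higher and 688 lower. The number called was 856 without LPS replicate 1 and 775 without LPS replicate 2, with 179 and 172 of them lower, and a fit of the compared groups alone gave 771 higher and 252 lower.

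The gingerol contrasts asked whether 6-gingerol altered the LPS-activated state. At 10 µM, Il6 was 168.1 ± 7.85 against 203.1 ± 13.1 CPM with LPS alone, a log2 difference of -0.27 (95% interval -0.59 to 0.05), and Tnf was 154.8 ± 3.69 against 149.4 ± 7.21 CPM (0.05, -0.14 to 0.24). The interferon-inducible Cxcl10 differed by -0.09 (-0.32 to 0.14) and Nos2 by -0.07 (-0.49 to 0.34). The antioxidant genes Gclm, the modifier subunit of glutathione synthesis, and Hmox1 differed by 0.03 (-0.18 to 0.23) and -0.04 (-0.27 to 0.19). With edgeR 0 genes were called, as with DESeq2, limma-voom and limma-trend. Without the count filter edgeR called 28 (15 higher and 13 lower). Among the filtered genes 243 (1.91%) had an unadjusted p under 0.05. Without any effect, exact p-values would put a fraction of about 0.05 of the genes there. The share found was smaller, so the edgeR test may have been conservative in this contrast. Its 0 calls therefore do not show that 6-gingerol had no effect. No list had a member called, over all genes or adjusted over the list alone. Camera called the interferon list lower (median -0.09, adjusted p = 0.00798; adjusted p = 0.387 with an estimated correlation) and mitochondrially encoded mRNAs higher (median 0.28, adjusted p = 6.99e-07; adjusted p = 0.636 with an estimated correlation).

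At 30 µM of 6-gingerol, Il6 stood at 109.4 ± 11.9 CPM, with a log2 difference from LPS of -0.89 (SE 0.15, 95% interval -1.22 to -0.57), the smallest adjusted p of the contrast at 0.378. Among other LPS-induced genes, Ccl2, a monocyte chemokine, differed by -0.39 (-0.73 to -0.05), Cxcl10 by -0.31 (-0.54 to -0.08), Cd14, the LPS co-receptor, by -0.39 (-0.64 to -0.13), Ptgs2 by -0.29 (-0.50 to -0.07) and Tnf by -0.14 (-0.33 to 0.04), none of them called. The neutrophil growth factor Csf3 was 1.41 ± 0.49 against 4.06 ± 0.86 CPM. Of the 17 cytokine genes 0 were called over all genes and 2, Il6 and Csf3, were lower when adjusted over the list alone. Camera called the cytokine list lower (median -0.23, adjusted p = 1.99e-09), and adjusted p = 0.111 with an estimated correlation. The inflammatory effectors had 0 members called either way, but their camera call (median -0.18, adjusted p = 1.62e-08) held, with adjusted p = 0.0389 with an estimated correlation, while fry gave 0.0573. Camera also called the interferon list lower (median -0.10, adjusted p = 0.00245), and the ribosomal proteins (0.000304), the respiratory chain (0.00245), mitochondrially encoded mRNAs (0.0029), NF-kB genes (0.0166), cholesterol biosynthesis (0.0166) and fibroblast markers (0.0491). None of these held, with adjusted p = 0.112, 0.66, 0.66, 0.643, 0.574, 0.642 and 0.571 with an estimated correlation. In total edgeR, limma-voom and limma-trend called 0 genes and DESeq2 called 2, Il6 among them. In edgeR 189 genes (1.49%) had an unadjusted p under 0.05. This share too lay below the fraction of 0.05 that exact p-values would give without an effect. The edgeR test may thus have been conservative here, and its 0 calls do not show that 6-gingerol had no effect. Without LPS replicate 1 edgeR called 1 gene. EdgeR called 27 genes without the count filter (10 higher and 17 lower), 4 in a fit of the compared groups alone (all lower) and 1 in a fit without the untreated libraries, with Il6 among them each time.

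The shogaol contrasts asked the same of 6-shogaol. At 10 µM, Il6 fell from 203.1 ± 13.1 to 29.2 ± 5.20 CPM, a log2 fold change of -2.80 (SE 0.17, adjusted p = 2.04e-07). Ccl5 fell by 1.91 on the log2 scale, to 71.3 ± 2.51 CPM. Cfb went to 84.3 ± 5.40 CPM (-1.65) and Cxcl10 to 82.6 ± 0.75 CPM (-1.60), both called. Tnf fell by 0.68, to 93.1 ± 5.44 CPM (SE 0.09, adjusted p = 0.0011). Nos2 was 131.4 ± 22.4 CPM (-0.54, adjusted p = 0.335) and Acod1 905.3 ± 67.9 CPM (-0.38, adjusted p = 0.238), neither of them called. Among antioxidant genes, Gclm, Hmox1, Txnrd1 and Srxn1 differed from LPS by 0.11 (95% interval -0.09 to 0.32), 0.00 (-0.23 to 0.23), 0.07 (-0.14 to 0.28) and 0.07 (-0.13 to 0.26).

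Interferon genes made up the largest called group of a list at 10 µM of 6-shogaol: 18 of 35 fell (28 adjusted over the list alone, median -0.82), Isg15 by 1.49, Oasl1 by 1.09, Rsad2 by 0.99 and Ifit1 by 1.39 on the log2 scale. In the cytokine list 8 of 17 fell (13 adjusted over the list alone, median -0.77). The monocyte chemokine Ccl2 and the interleukin 1 receptor antagonist Il1rn had log2 fold changes of -1.23 and -1.29. Of the effectors 7 of 26 fell (13 adjusted over the list alone, median -0.50), Marco by 0.83. Camera called these 3 lists lower (adjusted p = 2.82e-44, 1.31e-22 and 8.41e-18), and the calls held with an estimated correlation. In the NF-kB list 2 of 24 fell (3 adjusted over the list alone, camera adjusted p = 0.185), with Traf1 at a log2 fold change of -1.27. Camera further called NRF2 targets (1 higher of 31, also 1 adjusted over the list alone), glycolysis (0 of 28, 5 higher adjusted over the list alone) and LXR targets (0 of 10, 1 adjusted over the list alone) higher, and the respiratory chain (0 of 30 either way) and ribosomal proteins (0 of 32 either way, median -0.24) lower, at adjusted p = 0.00638, 8.26e-06, 0.000676, 0.000924 and 2.41e-08. None of these 5 held, with adjusted p = 0.278, 0.499, 0.278, 0.532 and 0.499 with an estimated correlation.

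At 10 µM of 6-shogaol 81 genes were called, 73 lower and 8 higher. The largest rise was that of Efr3b, a plasma membrane scaffold, with a log2 fold change of 0.86 (adjusted p = 0.0055), and that of Rasgrp3, a Ras activator, was 0.70 (adjusted p = 0.00188). Without LPS replicate 1 or 2 or 6-shogaol replicate 1 or 2 the adjusted p of Efr3b was 0.109, 0.0695, 0.0592 and 0.125, and that of Rasgrp3 was 0.0592 without 6-shogaol replicate 2. The number of genes called without those 4 libraries in turn was 44, 29, 32 and 18, of which 3, 1, 1 and 0 were higher. It also depended on the method: 970 (346 higher and 624 lower) in a fit of the compared groups alone, 311 without the count filter, 167 without the untreated libraries, 120 with DESeq2 and 34 with limma-trend on the authors' table. The 10 µM 6-shogaol libraries had mean fragments 17.5 bases longer than the LPS libraries, and 48 genes were called with fragment length as a covariate.

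At 30 µM of 6-shogaol, Il6 fell further, to 3.52 ± 0.84 CPM, a log2 fold change of -5.84 (SE 0.21, adjusted p = 1.28e-10). In untreated cells it was at 8.04 ± 2.42 CPM. Cfb fell by 5.14 on the log2 scale, to 7.48 ± 0.22 CPM. Ccl5 went to 18 ± 4.88 CPM (-3.89), and the NF-kB adaptor Traf1 (ENSMUSG00000026875, chromosome 2, 34941750 to 34961772) to 2.85 ± 0.20 CPM (-3.82), both called. Nos2 fell by 2.37, to 37.2 ± 12.9 CPM, Ptgs2 fell by 2.49, to 14.8 ± 0.05 CPM, and Tnf fell by 1.88, to 40.5 ± 0.43 CPM. Among genes that reached 5 CPM, called rises included those of Gsta3, a glutathione transferase (1.61 ± 0.14 to 9.72 ± 1.40 CPM, log2 fold change 2.58), Rmi2 (ENSMUSG00000037991, chromosome 16, 10835059 to 10892966), a subunit of the BLM helicase complex (2.57), Cdc6, a replication licensing factor (1.99), cyclin E2, encoded by Ccne2 (1.85), and the constitutive chaperone Hspa8 (ENSMUSG00000015656, chromosome 9, 40800984 to 40810087), which rose from 698.1 ± 4.53 to 2434 ± 37.3 CPM (1.80, SE 0.11, adjusted p = 5.54e-08).

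Inflammatory genes fell at 30 µM of 6-shogaol. Of 17 cytokine genes 16 fell (16 adjusted over the list alone, median -2.17), and Il18 was not called at 4.33 against 3.44 CPM. Effectors fell in 23 of 26 cases (23 adjusted over the list alone, median -1.12), with Marco at -2.62 and Saa3 at -2.41, and 2 rose. Interferon genes fell in 26 of 35 cases and 1 rose (27 and 1 adjusted over the list alone, median -1.40), with Isg15 at -2.48, Rsad2 at -1.52 and Gbp2 at -3.14. Camera called the 3 lists lower (adjusted p = 4.76e-18, 1.09e-17 and 3.2e-19), and each call held with an estimated correlation. In the NF-kB list 13 of 24 fell, with Cd40 at -1.55 and the ubiquitin ligase Birc3 at -1.05, and 2 rose (13 and 4 adjusted over the list alone). Its camera call (adjusted p = 4.86e-05) became adjusted p = 0.085 with an estimated correlation.

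Some genes that moved against their lists at 30 µM of 6-shogaol were named after their values were seen. The surface protein Cd83 rose by 0.77 on the log2 scale (adjusted p = 0.00244), and its call held without any 1 library. The arginine transporter Slc7a2 rose by 0.44 (0.00475) and was at adjusted p = 0.0655 without LPS replicate 1. The protease Casp1 (0.45) and the kinase Map3k8 (0.45) were called at 0.0389 and 0.0185. Without LPS replicate 1 they were at 0.193 and 0.0969, without LPS replicate 2 at 0.109 and 0.0951, and without 6-shogaol replicate 2 at 0.326 and 0.1. Among stress genes, the amino acid transporter Slc7a5 rose by 0.39 (0.0449) and the ubiquitin gene Ubb fell by 0.41 (0.0285). Without LPS replicate 1, LPS replicate 2 and 6-shogaol replicate 1 they were at 0.196, 0.132 and 0.36 (Slc7a5) and at 0.137, 0.0963 and 0.0626 (Ubb), and Ubb was at 0.17 without 6-shogaol replicate 2.

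Genes of DNA replication and G1/S rose almost throughout: 26 of 28 (26 adjusted over the list alone), with a median log2 fold change of 1.04 (camera adjusted p = 1.74e-25, held with an estimated correlation). The helicase subunit Mcm5 (ENSMUSG00000005410, chromosome 8, 75109569 to 75128439) rose from 66.9 ± 2.04 to 229.4 ± 17.4 CPM (1.78, SE 0.12, adjusted p = 7.19e-08). The ribonucleotide reductase subunit Rrm1 rose from 115.4 ± 0.64 to 359.6 ± 30.5 CPM, and Mcm4 rose by 1.47 on the log2 scale. NRF2 targets rose in 20 of 31 cases and none fell (21 and 2 adjusted over the list alone, median 0.44). Gclm (ENSMUSG00000028124, chromosome 3, 122245557 to 122270732) rose from 62.4 ± 2.19 to 137.8 ± 2.97 CPM. Me1, which supplies NADPH, catalase (Cat) and glutathione reductase (Gsr) had log2 fold changes of 1.17, 1.00 and 0.85. Hmox1 was 433.3 ± 58.1 against 524.5 ± 25 CPM and was not called (adjusted p = 0.0753), but it was called without 6-shogaol replicate 1. HSF1 targets rose in 10 of 22 cases (11 adjusted over the list alone, median 0.36), with the co-chaperone Hsph1 at 1.05 and Hspa4 at 0.62, and 1 fell (1 adjusted over the list alone). The stress-inducible Hspa1a (1.15 against 0.76 CPM) and Dnajb1 (27.6 against 23.5 CPM) were not called. Camera called both lists higher (adjusted p = 2.46e-10 and 2.08e-05), and the calls held with an estimated correlation. Cholesterol biosynthesis genes rose in 15 of 23 cases (16 adjusted over the list alone, median 0.52, camera adjusted p = 4.23e-08), with adjusted p = 0.0516 with an estimated correlation. Insig1 (ENSMUSG00000045294, chromosome 5, 28071363 to 28078662), the sterol-responsive retention protein of SREBP, rose from 128.2 ± 15.6 to 277.2 ± 15.6 CPM. Acat2 rose by 1.22 on the log2 scale.

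Immediate early genes fell at 30 µM of 6-shogaol in 16 of 27 cases (18 adjusted over the list alone, median -0.79, camera adjusted p = 2.49e-11, held with an estimated correlation), with Ier3 at -1.52 and Jund at -1.31. ATF4 targets fell in 14 of 34 cases and 1 rose (16 and 1 adjusted over the list alone, median -0.33), but the camera call (adjusted p = 8.54e-06) became adjusted p = 0.202 with an estimated correlation. Ppp1r15a (ENSMUSG00000040435, chromosome 7, 45522916 to 45526268), the phosphatase subunit that reverses eIF2α phosphorylation, fell from 101.7 ± 9.53 to 16.5 ± 1.84 CPM, and the stress-induced regulators Trib3, Ddit3 and Atf3 had log2 fold changes of -2.003, -1.87 and -1.304. Mitosis genes rose in 12 of 24 cases and Ccnb2 fell (13 and 1 adjusted over the list alone), and glycolysis and hypoxia genes fell in 10 of 28 (10 adjusted over the list alone), with Hilpda at -1.437. Fibroblast and endothelial markers fell in 2 of 3 cases (2 adjusted over the list alone), Col1a1 being at 0.20 against 1.48 CPM. Camera called these 3 lists at adjusted p = 0.000326, 0.00391 and 0.0435, and none held, with adjusted p = 0.202, 0.442 and 0.202 with an estimated correlation. Lists without a camera call had members called higher and lower as well: 2 and 6 of 20 p53 targets (3 and 7 adjusted over the list alone), with Mdm2 at -1.52, 5 and 1 of 22 unfolded protein response chaperones (6 and 1), 5 and 2 of 10 LXR targets (5 and 2) and 6 and 3 of 25 microglia identity genes (8 and 5). Lysosome and autophagy had 6 and 5 of 30 (6 and 5), metallothioneins and zinc 3 and 1 of 6 (3 and 1), the respiratory chain 5 and 0 of 30 (5 and 0) and mitochondrially encoded mRNAs 0 and 1 of 13 (0 and 1). No ribosomal protein was called either way, with a median log2 fold change of -0.12.

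In total 3222 genes were called at 30 µM of 6-shogaol, 1601 higher and 1621 lower, and at a log2 fold change of at least 1 there were 162 higher and 454 lower. Of the 973 genes raised by LPS, 557 (57.2%) were lower and 43 higher. The 11204 genes not called with LPS gave 1376 higher and 1040 lower, 75% of all calls. The number called was 1835 without LPS replicate 1, 1850 without LPS replicate 2 and 2112 without 6-shogaol replicate 2.

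**Figure D2:**
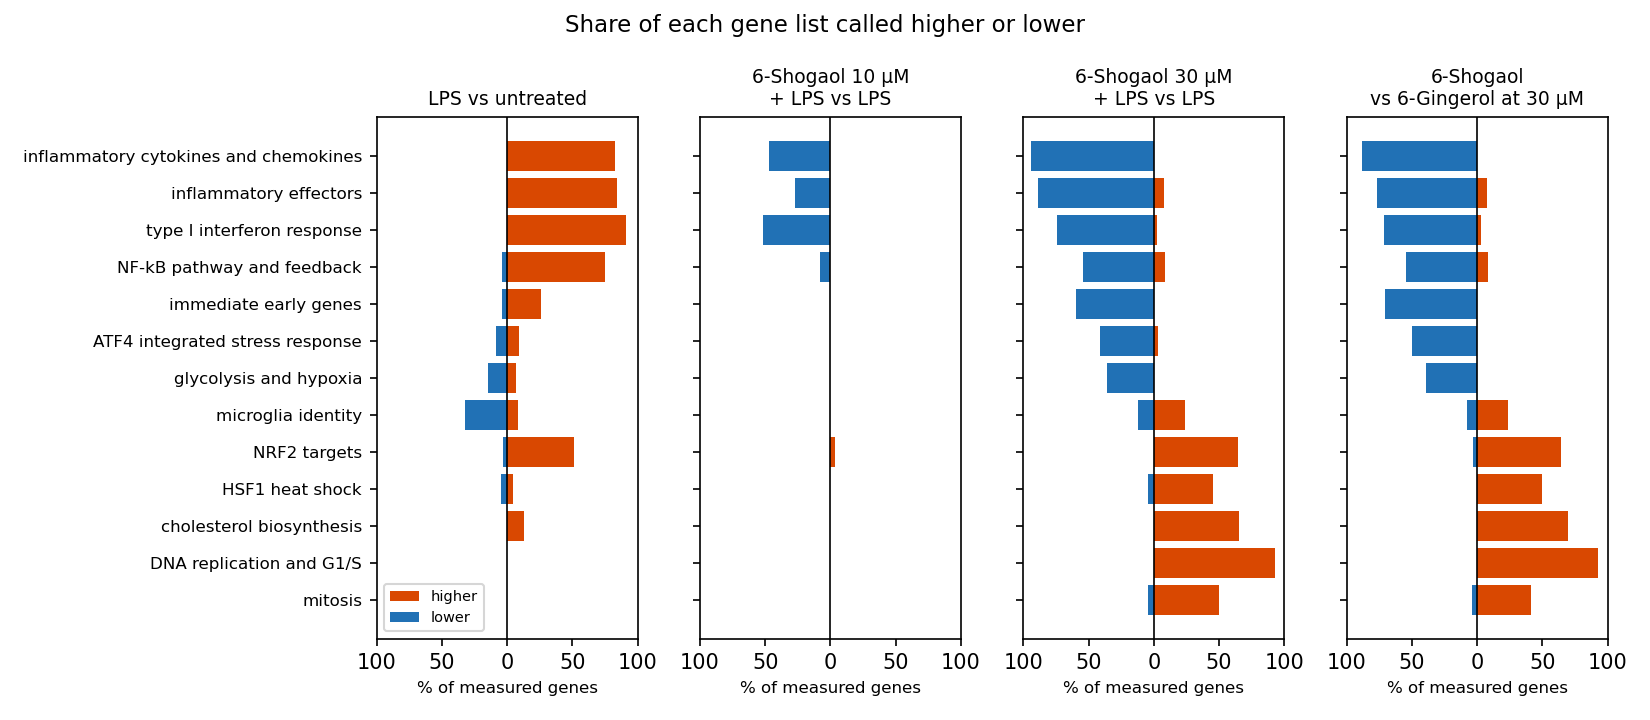
Share of the measured members of each list called higher (right) or lower (left) by edgeR, in percent, for the contrasts named above each panel. At 30 µM of 6-shogaol 16 of 17 cytokine genes are lower and 26 of 28 replication genes higher.

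The LPS-induced genes were followed as a set, to ask how much of the LPS response was left with each compound. LPS induced 370 genes at a log2 fold change of at least 1. With 6-gingerol edgeR called 0 of them lower at 10 and at 30 µM. DESeq2 called 0 and 2 of all genes in those contrasts, and 243 and 189 of all genes had an unadjusted p under 0.05. Both counts lie below a fraction of 0.05 of the genes tested. The 0 calls therefore do not show that the LPS-induced genes were unchanged. With 6-shogaol 63 of them were lower at 10 µM and 279 (75.4%) at 30 µM, and 6 others rose further at 30 µM of 6-shogaol: Gsta3, Me1, the sterol sensor Insig1, Atf7ip2, Gsr and Slc7a11. These 6 were named after their values were seen, and Slc7a11 (0.37) and Atf7ip2 (0.97) were not called without LPS replicate 1 (adjusted p = 0.273 and 0.144) or 6-shogaol replicate 2 (0.191 and 0.139). The median retained response was 96.5% with 10 µM 6-gingerol, 94.3% with 30 µM 6-gingerol, 75.1% with 10 µM 6-shogaol and 42.9% with 30 µM 6-shogaol, against simulated means of 97.9, 97.7, 97.8 and 97.9% for unchanged groups, whose lowest values were 96.6, 96.3, 96.6 and 96.2%. Computed per replicate the means were 96.8 ± 0.6, 93.8 ± 0.1, 75.8 ± 1.0 and 42.9 ± 0.2%. Log2 fold changes lay below 0 for 67.6, 75.4, 90.0 and 94.6% of the 370 genes, where simulated unchanged groups reached at most 63.2, 63.1, 63.0 and 63.7%. Simulated genes varied independently, so these simulated ranges are too narrow for genes that vary together. The count of 63 was 38 and 28 without LPS replicate 1 and 2 and 30 and 18 without 6-shogaol replicate 1 and 2.

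Among the 79 genes lowered by LPS, 6-shogaol raised 1 at 10 µM, Rasgrp3, and at 30 µM it raised 28 and lowered 4 more (Thbs1, Cyp4f18, Fos and Gpr35, named after their values were seen). Thbs1 was not called without LPS replicate 2 (adjusted p = 0.363) or 6-shogaol replicate 1 or 2 (0.166 and 0.0589), and Cyp4f18 not without LPS replicate 1 (0.0663) or 6-shogaol replicate 2 (0.116). Rasgrp3 went from 112.4 CPM untreated to 55.4 with LPS, 90.1 with 10 µM and 126.7 with 30 µM 6-shogaol. Without replicate 2 of 10 µM 6-shogaol Rasgrp3 was not called at that dose (adjusted p = 0.0592). Apoe went from 184.2 ± 0.19 with LPS to 306.0 ± 14.9 CPM at 30 µM, against 425.8 ± 18.3 CPM untreated. With 6-gingerol the median retained response of these 79 genes was 88.1% at 10 µM and 82.6% at 30 µM, with simulated means of 86.5 and 86.6%. With 6-shogaol it was 66.1 and 59.3%, with simulated means of 86.7 and 87.2%.

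**Figure D3:**
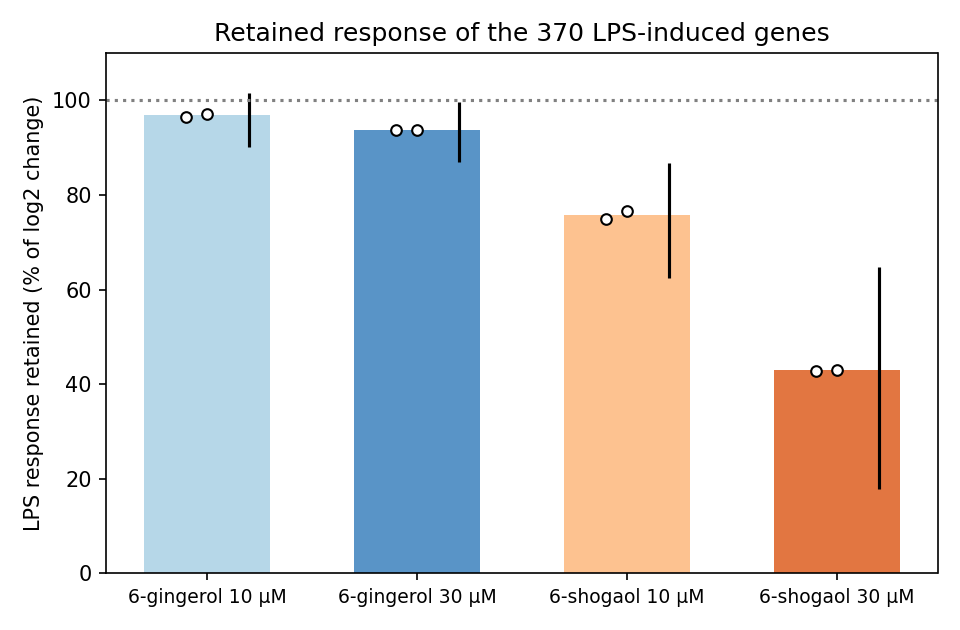
Retained LPS response of the 370 LPS-induced genes, in percent of the log2 change with LPS alone, for each compound and dose, with points for the 2 replicates, bars for their mean and a vertical line for the interquartile range over genes. The means are 96.8 and 93.8% with 6-gingerol and 75.8 and 42.9% with 6-shogaol at 10 and 30 µM.

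**Figure D4:**
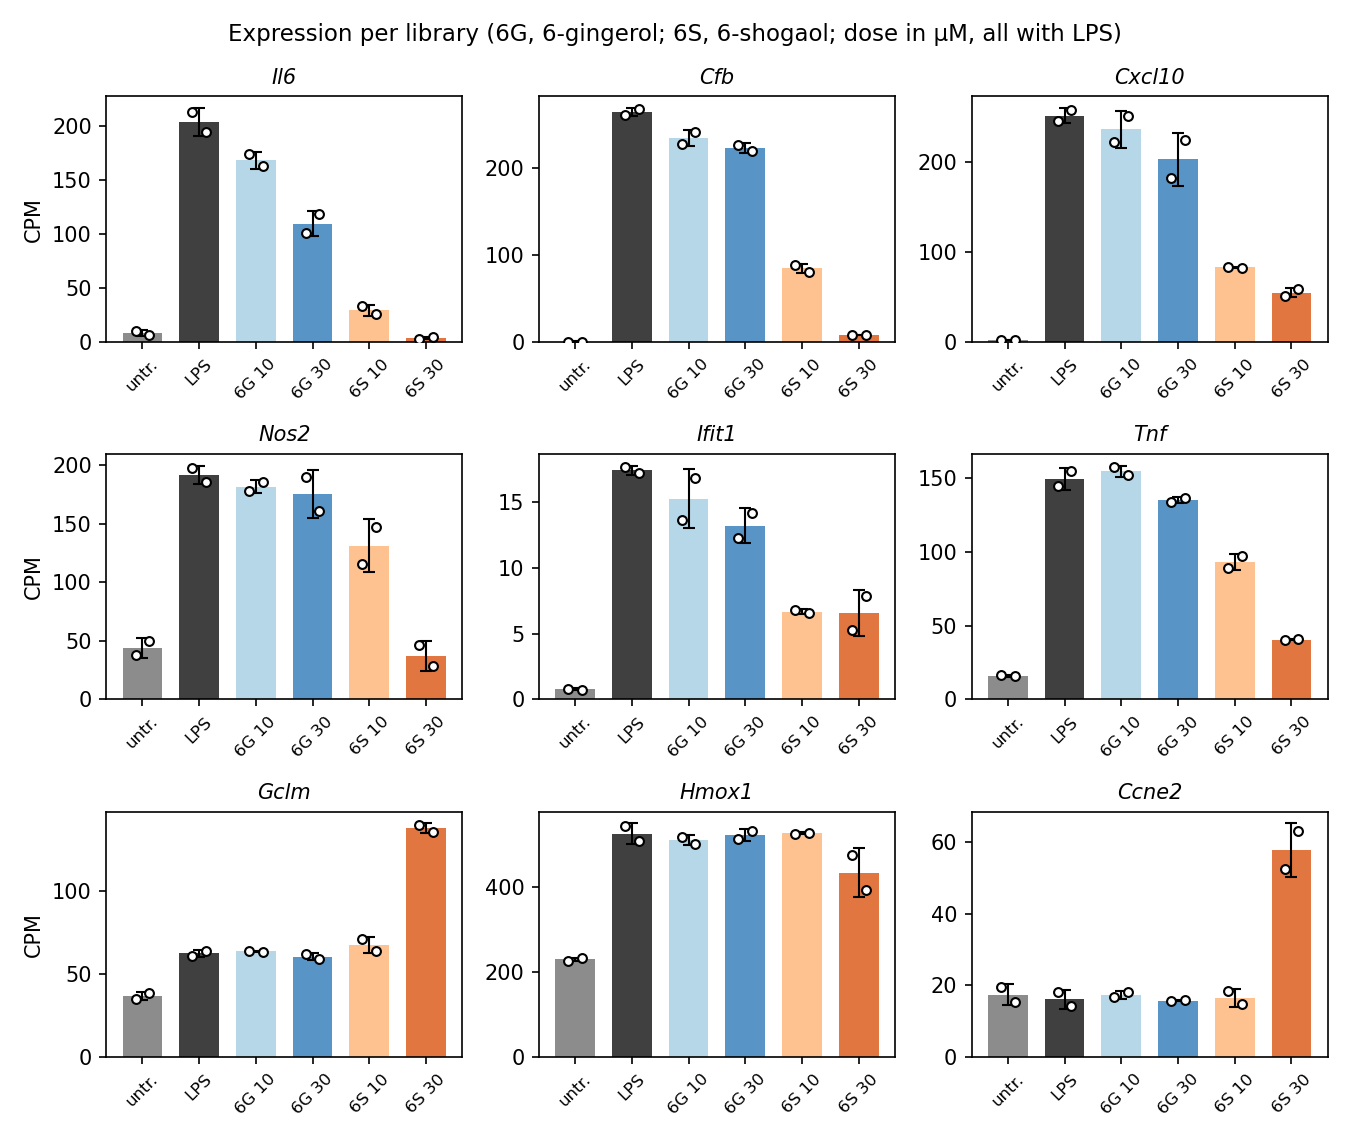
CPM per library of selected genes in the 6 groups, each point 1 library, each bar the group mean and each error bar 1 SD. Il6 lies near 203 CPM with LPS, 109 with 30 µM 6-gingerol and 3.52 with 30 µM 6-shogaol.

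Next the compounds were set against each other at 10 µM. Il6 was 29.2 ± 5.20 CPM with 6-shogaol and 168.1 ± 7.85 with 6-gingerol, a log2 difference of -2.53 (95% interval -2.88 to -2.18, adjusted p = 8.02e-07). Ccl5 differed by -1.66 (-2.05 to -1.26), Cxcl10 by -1.51 (-1.75 to -1.27), Il1rn by -1.48 (-1.78 to -1.18), Cfb by -1.47 (-1.67 to -1.28) and Tnf by -0.73 (-0.92 to -0.54), all called. Gclm differed by 0.09 (-0.12 to 0.29), Hmox1 by 0.05 (-0.18 to 0.28) and Nos2 by -0.47 (-0.88 to -0.05), none of them called. Interferon genes were lower with 6-shogaol in 18 of 35 cases (27 adjusted over the list alone), cytokines in 8 of 17 (12) and effectors in 6 of 26 (10). Camera called these 3 lists (adjusted p = 2.38e-32, 5.96e-18 and 9.29e-13), and the calls held with an estimated correlation. NRF2 targets (1 higher, 4 adjusted over the list alone), LXR targets (0, 3 adjusted over the list alone) and glycolysis genes (0, 3 adjusted over the list alone) were called higher by camera and mitochondrially encoded mRNAs (0, 3 lower adjusted over the list alone), the respiratory chain and ribosomal proteins (none called either way) lower, at adjusted p = 0.0225, 0.00289, 0.00246, 3.21e-05, 0.0019 and 3.78e-06, but none held, with adjusted p = 0.364, 0.358, 0.564, 0.364, 0.564 and 0.55 with an estimated correlation. In all 81 genes were called, 71 lower and 10 higher with 6-shogaol. Tspoap1, the largest positive difference at 1.011, was at adjusted p = 0.174 without 6-gingerol replicate 1, 0.0769 without 6-shogaol replicate 1 and 0.271 without 6-shogaol replicate 2. Scaling by library totals shifted the median of all genes by 0.11 and gave 21 higher and 48 lower, and the count was 31 and 49 without 6-gingerol replicate 1 and 2 and 23 and 16 without 6-shogaol replicate 1 and 2, of which 0, 9, 0 and 0 were higher. It was 419 without the count filter, 257 without the untreated libraries, 179 with DESeq2, 170 with the compared groups alone and 41 with limma-trend on the authors' table.

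At 30 µM the compounds differed in more genes. Il6 differed by -4.95 (95% interval -5.39 to -4.51), Cfb by -4.89 (-5.13 to -4.65), Ccl5 by -3.65 (-4.09 to -3.22), Traf1 by -3.46 (-3.80 to -3.12), Tnf by -1.74 (-1.94 to -1.54) and Nos2 by -2.24 (-2.68 to -1.80), all called lower with 6-shogaol. Called higher were Rmi2 at 2.42 (1.93 to 2.90), Gsta3 at 2.23 (1.59 to 2.87), the calcium-binding S100a4 at 1.89 (1.66 to 2.13), Ccne2 at 1.88 (1.55 to 2.21), Hspa8 at 1.73 (1.49 to 1.97) and Gclm at 1.19 (0.98 to 1.40). Hmox1 differed by -0.27 (-0.50 to -0.04) and was not called (adjusted p = 0.084), but it was at 0.0376 without 6-shogaol replicate 1. Among lists, 26 of 28 replication genes (26 adjusted over the list alone), 20 of 31 NRF2 targets (23, with 1 lower over all genes and 2 over the list alone), 11 of 22 HSF1 targets (13, with 1 lower over the list alone) and 16 of 23 cholesterol genes (17) were higher with 6-shogaol, and 15 of 17 cytokines (16), 20 of 26 effectors (23, with 2 higher either way), 25 of 35 interferon genes (26, with 1 higher either way) and 19 of 27 immediate early genes (19) were lower, each a camera call that held with an estimated correlation. The calls of NF-kB (13 lower and 2 higher of 24, 13 and 3 adjusted over the list alone), ATF4 (17 lower of 34, 17 adjusted over the list alone), glycolysis (11 lower of 28, 11 adjusted over the list alone), mitosis (10 higher and 1 lower of 24, 14 and 1 adjusted over the list alone) and the respiratory chain (6 higher of 30, 6 adjusted over the list alone) became adjusted p = 0.118, 0.192, 0.497, 0.174 and 0.572 with an estimated correlation. In all 3171 genes were called, 1592 higher and 1579 lower, with 157 and 393 at a log2 difference of at least 1. With library totals 1265 were higher and 1653 lower. The count was 1819 without 6-gingerol replicate 1 and 1878 without 6-shogaol replicate 2.

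The dose contrasts asked what changed from 10 to 30 µM. With 6-shogaol, Cfb fell by 3.49 on the log2 scale (SE 0.11, adjusted p = 4.38e-11), Il6 by 3.04, the chemokine Cxcl2 by 2.82 and Traf1 by 2.56. Rmi2, the calcium-binding S100a11, Ccne2 and Cdc6 rose by log2 fold changes of 1.97, 1.89, 1.82 and 1.81. Ifit1 was 6.67 ± 0.19 CPM at 10 µM and 6.57 ± 1.78 at 30 µM, a difference of -0.01 (95% interval -0.41 to 0.39). Replication genes rose in 26 of 28 cases (27 adjusted over the list alone), cholesterol genes in 15 of 23 (16), NRF2 targets in 17 of 31 (18, with 1 lower over all genes and 2 over the list alone) and HSF1 targets in 7 of 22 (9), and immediate early genes fell in 20 of 27 (22), cytokines in 14 of 17 (15), effectors in 16 of 26 (18, with 2 higher either way) and interferon genes in 17 of 35 (20, with 2 higher either way), each a camera call that held with an estimated correlation. Calls that did not hold were those of ATF4 (13 lower of 34, 15 adjusted over the list alone), mitosis (11 higher and 1 lower of 24, 11 and 1), NF-kB (12 lower of 24, 12 and 1 higher), unfolded protein response (8 higher and 1 lower of 22, 9 and 1), glycolysis (14 lower of 28, 14 and 1 higher) and respiratory chain genes (9 higher of 30, 9), with adjusted p = 0.124, 0.124, 0.0604, 0.085, 0.179 and 0.432 with an estimated correlation. In all 2463 genes were called, 1251 higher and 1212 lower, with 111 and 243 at a log2 fold change of at least 1. Scaling by library totals gave 870 higher and 1434 lower, and the count was 1252 and 969 without replicate 1 and 2 of 10 µM 6-shogaol and 1154 without replicate 2 of 30 µM 6-shogaol.

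With 6-gingerol 1 gene was called between the doses, mt-Nd3 (ENSMUSG00000064360, mitochondrial genome, 9459 to 9806), a subunit of respiratory complex I, at 41.6 ± 6.99 CPM at 30 µM and 85.9 ± 17.8 at 10 µM (log2 fold change -1.05, SE 0.14, adjusted p = 0.0315). It was not called without 10 µM replicate 1 (adjusted p = 0.905) or 30 µM replicate 2 (0.824), or with library totals or limma-trend on the authors' table, where 0 genes were called. DESeq2 and limma-voom each called 1 gene. EdgeR called 49 without the count filter (20 higher and 29 lower) and 7 with the compared groups alone (2 higher and 5 lower). Here 434 genes (3.42%) had an unadjusted p under 0.05, which is again less than a fraction of 0.05. The cytokine Il6 differed by -0.62 (95% interval -0.94 to -0.30) and Tnf by -0.20 (-0.38 to -0.01), neither of them called. Camera called mitochondrially encoded mRNAs lower (8 of 13 adjusted over the list alone, adjusted p = 2.84e-10), cytokines (1 lower adjusted over the list alone, 9.81e-05), effectors (0.00958), the respiratory chain (0.0121) and ribosomal proteins (0.0341), and none held, with adjusted p = 0.32, 0.32, 0.32, 0.849 and 0.849 with an estimated correlation.

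Whether the dose step itself depended on the compound was tested as a difference of the dose steps, 6-shogaol minus 6-gingerol. Cfb had a difference of -3.42 (SE 0.14, adjusted p = 2.27e-09), Cxcl2 -2.67 (SE 0.20, 2.28e-06), Il6 -2.42 (SE 0.26, 9.3e-05) and Tnf -1.004 (SE 0.13, 0.000321). The snoRNA host gene Snhg12 had -2.45 (2.28e-06) and Ppp1r15a -2.37 (2.28e-06). Called positive differences included Rmi2 at 2.33 (SE 0.34, 0.000986), S100a11 at 2.13 (SE 0.20, 1.93e-05), Dscc1, a loader of the replication clamp, at 2.05 (SE 0.30, 0.000955) and Ccne2 at 1.96 (SE 0.22, 0.000125), with Mcm4 at 1.60 (1.13e-05), Hspa8 at 1.441 (0.000103) and Gclm at 1.11 (0.000246). Cxcl10 at -0.38 (0.151), Ifit1 at 0.19 (0.667) and Hmox1 at -0.31 (0.22) were not called. Replication genes had higher differences in 22 of 28 cases (26 adjusted over the list alone, median 1.02, camera adjusted p = 2.88e-29), cholesterol genes in 12 of 23 (16), NRF2 targets in 10 of 31 (16, with 1 lower) and HSF1 targets in 4 of 22 (6). Immediate early genes had lower differences in 16 of 27 cases (19), cytokines in 10 of 17 (10), effectors in 9 of 26 (12, with 1 higher either way) and interferon genes in 9 of 35 (18, with 1 higher either way). These 8 camera calls held with an estimated correlation. Those of mitosis (8 higher of 24, 10 adjusted over the list alone), ATF4 (6 lower of 34, 12), glycolysis (10 lower of 28, 14), NF-kB genes (9 lower of 24, 10), the unfolded protein response (3 higher of 22, 7), the respiratory chain (2 higher of 30, 9), mitochondrially encoded mRNAs (2 higher of 13, 3) and ribosomal proteins (none of 32 either way, median 0.20) became adjusted p = 0.107, 0.16, 0.301, 0.0996, 0.0859, 0.336, 0.464 and 0.576 with an estimated correlation. In edgeR 1038 genes were called, 542 higher and 496 lower, with 113 and 177 at an absolute log2 difference of at least 1. With library totals the median of all genes shifted by -0.15 and the calls were 262 higher and 759 lower. The count was 1730 without the untreated libraries, 576 with limma-trend on the authors' table, 475 without replicate 1 of 10 µM 6-gingerol, 356 without replicate 1 of 30 µM 6-gingerol, 404 and 299 without replicate 1 and 2 of 10 µM 6-shogaol, and 348 without replicate 2 of 30 µM 6-shogaol.

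The calls of the shogaol doses overlapped: of 8 genes higher at 10 µM all 8 were higher at 30 µM, where 1.008 would be shared by independent lists, and of 73 lower genes 72 were lower at 30 µM, where 9.31 would be. The doses shared the LPS libraries, which alone gives correlated changes. Over all genes with a CPM of at least 5 the log2 fold changes correlated at 0.497, against a mean of 0.491 (0.179 to 0.689) in simulated unchanged groups. The covariance was 0.0446, against a simulated mean of 0.0154 and a highest value of 0.0262. In simulated unchanged groups a mean of 0.025 genes was lower at both doses and 0.05 higher at both, with at most 1 each. Those groups had means of only 0.2 and 0.2 genes called lower at 10 and 30 µM and 0.2 and 0.3 higher. Their overlap therefore had to be near 0 and decides nothing about the 72 and 8 genes. The covariance argues against the shared libraries alone as the source of the common changes over all genes, although the correlation showed no excess. How much of the overlap of calls comes from the shared libraries was not obtained. Between the compounds there was no overlap to compare, since edgeR called 0 genes with 6-gingerol.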

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

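Tests of library scaling, fragment length, shared LPS libraries and a weaker LPS response were chosen only after the result was seen, and those of GC content, gene length and AU-rich motifs before it.

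The step from 10 to 30 µM differed between the compounds, by a test of the difference itself, for 1038 genes, and this difference between groups called for a closer look. The replication genes Rmi2 and Dscc1 had differences of 2.33 and 2.054 on the log2 scale, and the calcium-binding S100a11 had 2.133. Cfb, Cxcl2 and the snoRNA host gene Snhg12 had -3.419, -2.665 and -2.448.

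A further signal lay in genes that only the authors' normalized table holds, so that the counts could not be used for them. Of 2031 such genes 678 passed the filter, and limma-trend called 22 with LPS (20 higher), 1 with 10 µM 6-shogaol (Gm42791, higher) and 70 with 30 µM 6-shogaol (13 higher and 57 lower). The guanylate-binding protein Gbp6 had a log2 difference of 3.117 with LPS (226.3 to 1952 normalized counts, SE 0.13, adjusted p = 9.26e-10). The snoRNA host gene Snhg1 had -2.577 at 30 µM of 6-shogaol (7086 to 1193 normalized counts, 6383 untreated, SE 0.16, adjusted p = 1.75e-07). These genes were named after their values were seen.

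The first pattern weighed was the rise of DNA replication and G1/S genes at 30 µM of 6-shogaol, among them Mcm5, Rrm1 and Ccne2. A scaling error could have moved every gene alike, but the list's median lay 1.047 above that of all other genes (28 genes, interquartile range 0.775 to 1.386), while the other scalings moved all genes by -0.002 and 0.003 and decided nothing. Bias from GC content or gene length left a median residual of 1.053 (0.849 to 1.407), and fragment length as a covariate left 1.03 (0.708 to 1.36), so these 3 technical explanations were excluded. A likely remaining source is the treatment itself, which may have shifted more cells towards S phase or raised these transcripts per cell. No test separated those possibilities, and cell numbers were not measured.

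The second pattern was the group of 81 genes called at 10 µM of 6-shogaol, among them Il6, Ccl5 and Isg15. Longer fragments might have given it, but the within-group slope on fragment length accounted for a median of 6.5% of the log2 fold change. Resampling the 81 genes gave a 95% interval of 3.9 to 9%. The genes are not independent, and this interval leaves out the uncertainty of the slope between libraries. With fragment length as a covariate the 81 genes had the same direction and 47 of them were still called. The median absolute log2 fold change was then 0.897 against 0.915 and the median SE 0.15 against 0.136. Chance differences in the shared LPS libraries could also have contributed. Against 6-gingerol at 10 µM, without those libraries, a median of 91.0% of the change was found (interquartile range 85.7 to 100.2%, 63 of the 81 also called there). Both contrasts use the same 10 µM 6-shogaol libraries, so some agreement would appear without an effect, and its size was not obtained. The values argue against fragment length and the LPS libraries as the main source, but do not exclude a part from either. An effect of 6-shogaol at this dose remains a hypothesis that rests on the group labels.

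The third pattern was the group of 3222 genes called at 30 µM of 6-shogaol, from Il6 and Cfb to Hspa8 and Gclm. A weaker LPS response alone was weighed, but 53.3% of the genes (51.5 to 55%, 1717 genes) also differed from untreated cells in the same direction. A first version of that test, the share with an unadjusted p of at least 0.05 for LPS against untreated, gave 59.7% (58 to 61.4%, 1924 genes). Both intervals are binomial over genes, which are not independent. The contrasts with LPS and with untreated cells use the same 30 µM 6-shogaol libraries, so some agreement would appear without an effect. The shares argue against a weaker LPS response as the only source. Faster loss or lower synthesis of mRNAs with AU-rich elements might explain the lower genes outside the LPS response. There 9.8% of 778 genes with the motif and 9.1% of the others were lower, with an odds ratio of 1.115 (0.864 to 1.4) against at most 1.274 for 20 shuffled motifs, so this explanation and its absence cannot be told apart.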

How the results depend on the processing

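Of the tests in this part, fragment length as a covariate, a fit without the untreated libraries and the bias-adjusted fit were chosen only after the result was seen. No named gene or list that was called in either setting changed direction. The balance of higher and lower calls turned with library totals, from 542 and 496 to 262 and 759 for the dose steps, from 1251 and 1212 to 870 and 1434 between the shogaol doses and from 1592 and 1579 to 1265 and 1653 between the compounds at 30 µM. Log2 fold changes of at least 1 turned it too, to 113 and 177, 111 and 243 and 157 and 393 in that order. The stricter filter gave 489 and 531, 1153 and 1193 and 1443 and 1504. The authors' table gave 917 and 927 between the shogaol doses and 1219 and 1251 between the compounds at 30 µM. For 30 µM 6-shogaol against LPS, 1601 and 1621 became 1490 and 1448 with DESeq2. They became 2039 and 2023 with the compared groups alone and 1886 and 1878 without the untreated libraries. Counting log2 fold changes of at least 1 left 449 genes with LPS, 34 and 616 with 10 and 30 µM 6-shogaol, 30 and 550 between the compounds at 10 and 30 µM, 354 between the shogaol doses and 290 for the difference of the dose steps, because a called gene then also had to be that large. Without a count filter there were 28 and 27 calls with 10 and 30 µM 6-gingerol, 311 with 10 µM 6-shogaol, 419 between the compounds at 10 µM and 49 between the gingerol doses. DESeq2 called 2 with 30 µM 6-gingerol and 179 between the compounds at 10 µM. A fit of the compared groups alone gave 4 with 30 µM 6-gingerol, 970 with 10 µM 6-shogaol, 170 between the compounds at 10 µM and 7 between the gingerol doses. The authors' table gave 34 with 10 µM 6-shogaol, 41 between the compounds at 10 µM, 0 between the gingerol doses and 576 for the dose steps. Fragment length gave 48 with 10 µM 6-shogaol. Without the untreated libraries there were 1 with 30 µM 6-gingerol, 167 with 10 µM 6-shogaol, 257 between the compounds at 10 µM and 1730 for the dose steps. Library totals gave 0 between the gingerol doses. For these values the cause was not tested. Of the LPS-induced genes, 30 µM 6-gingerol retained 94.0% at a log2 fold change of at least 2, 94.4% with DESeq2 size factors and 94.4% with fragment length. At 10 µM of 6-shogaol 40 of those induced by at least 2 were lower, and 77.6% was retained with fragment length. At 30 µM it was 116, with 44.7% retained at a log2 fold change of at least 2, 42.0% with a replicate term and 41.8% with fragment length. The smaller counts follow from fewer genes, and for the retained values the cause was not tested.

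Leaving out 1 library at a time gave 775 to 1614 genes with LPS, 0 to 1 with 30 µM 6-gingerol, 18 to 44 and 1835 to 2197 with 10 and 30 µM 6-shogaol, 16 to 49 and 1819 to 2169 between the compounds, 969 to 1681 between the shogaol doses and 299 to 839 for the dose steps. The cause was not tested, and the count with LPS rose from 1501 to 1614 without untreated replicate 1. LPS-induced genes lowered were 0 to 1 with 30 µM 6-gingerol (1 without either untreated library), 18 to 91 with 10 µM 6-shogaol and 212 to 282 with 30 µM, and retained responses 95.4 to 97.8, 92.8 to 95.8, 74.0 to 79.9 and 42.0 to 48.5%. Named genes whose call was lost in at least 1 such fit numbered 15 of 76 with LPS, 16 of 30 and 18 of 99 with 10 and 30 µM 6-shogaol, 20 of 31 and 18 of 99 between the compounds, 18 of 89 and 1 of 1 between the shogaol and gingerol doses and 26 of 76 for the dose steps. Among 220 camera tests 56 were weaker with an estimated correlation, and with fry 33 were weaker and 16 stronger, and 2 that neither called changed sign (immediate early genes at 10 µM of 6-shogaol and microglia identity between the gingerol doses). The bias-adjusted fit gave 1520, 79 and 3237 genes with LPS and with 10 and 30 µM 6-shogaol, of which 1492, 77 and 3203 were shared with the fit described. A replicate term gave 1541, 80 and 3262, and the replicate numbers did not pair libraries, with correlations of replicate differences between -0.054 and 0.178 for compared groups and down to -0.312 among all pairs. In data simulated with 2 libraries per group at these depths, 43.3 to 58.2% of 1.5-fold changes were recovered. Neither depth nor the number of libraries was varied. The share can be lower where fewer genes change than were simulated, since the adjustment is then stricter. It therefore does not give the share that the 6-gingerol contrasts could have found.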

Other observations

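The test of the interferon genes described here was chosen only after the result was seen, and the gene families were chosen after their values were seen.

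At 30 µM of 6-shogaol host genes of small nucleolar RNAs fell in 6 of 10 cases. Snhg12 fell from 64.7 ± 3.23 to 9.56 ± 0.13 CPM (log2 fold change -2.76, SE 0.13, adjusted p = 2.18e-09), Zfas1 from 253.5 ± 5.98 to 68.9 ± 4.42 CPM (-1.88, SE 0.16) and Snhg5 from 107.3 ± 4.2 to 26.5 ± 8.24 CPM (-2.02, SE 0.35). Genes with a Dusp symbol (dual-specificity phosphatases) fell in 9 of 20 cases, Dusp1 from 10.0 ± 0.46 to 4.00 ± 0.48 CPM. Krüppel-like factors fell in 6 of 11 cases, Klf6 from 201.8 ± 7.38 to 80.5 ± 4.84 CPM and Klf2 from 15.8 ± 0.98 to 6.11 ± 0.52 CPM. Tubulins rose in 6 of 10 cases, Tuba1b from 857.6 ± 11.3 to 1507 ± 3.40 CPM. Of 37 proteasome subunits 10 rose, Psmd1 going from 94.7 ± 2.71 to 220.7 ± 3.80 CPM, and 4 fell, Psmb6 going from 700.3 ± 50.6 to 386.2 ± 23.5 CPM. The calls of the genes given with CPM held without any 1 of the 4 libraries. Those of every risen proteasome subunit except Psmd1 were lost in at least 1 such fit. Also lost were those of Gas5 (-0.92), Snhg6 (-0.376), Snhg17 (-0.474), Tubb1 (-0.65), Tuba1a (0.487) and Psmd8 (-0.341). The calls of Dusp11 (-0.425), Dusp12 (-0.503), Dusp14 (-0.652), Dusp18 (-0.455), Klf10 (-0.388), Klf13 (-0.478) and the chaperonin subunit Cct3 (-0.48) were lost as well.

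Interferon and inflammatory genes differed in how much of the 30 µM decline was present at 10 µM of 6-shogaol. Only list members called higher with LPS, at any fold change, and called lower at 30 µM of 6-shogaol were compared, so the values of this paragraph hold for them alone. For 26 such interferon genes the median share was 59.2% (interquartile range 49.3 to 71.1%), for 14 such cytokine genes 44.3% and for 20 such effector genes 32.6%. The median difference between interferon genes and the others was 20.3 points (permutation p = 0.00022, 2-sided, 100000 permutations of genes, which are not independent). Leaving out 1 library at a time gave 53.7 to 61.6% for interferon genes and 36.9 to 41.2% for the others. The interferon genes may have been back at the untreated level already at 10 µM, which would have left no room for a further decline. For these 26 genes as a set that was excluded, since a median of 69.7% of their LPS response (interquartile range 58.7 to 77.2%) was retained at 10 µM and 45.9% at 30 µM. Cytokine genes retained 65.9 and -14.1%, the latter below the untreated level, and effector genes 80.9 and 48.2%. Median log2 fold changes at 10 and 30 µM were -1.071 and -1.953 for interferon, -0.895 and -2.532 for cytokine and -0.586 and -1.391 for effector genes. The shares thus do not show that interferon genes lost more of their LPS response at 10 µM than cytokine genes.

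Against untreated cells, a contrast that was not planned, 30 µM 6-shogaol with LPS had 1696 genes called higher and 1533 lower. Of the 1601 genes higher than with LPS 956 were also higher than in untreated cells, and of the 1621 lower genes 761 were also lower. Summed CPM of marker genes of other cells was 65.28 to 108.13 for astrocytes, 0 to 0.44 for neurons, 1.16 to 3.19 for oligodendrocytes, 0.51 to 2.85 for fibroblasts and endothelium and 1.55 to 3.27 for lymphocytes and neutrophils. The astrocyte-list genes Aldoc and Gja1 were at 91.2 and 9.41 CPM with 30 µM 6-shogaol against 64.8 and 16.2 with LPS. Mitochondrially encoded transcripts made up 4.995 to 6.912% of the counts of a library.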
